A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

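Chromatin immunoprecipitation on tiling arrays was analysed for 4 samples of Schizosaccharomyces pombe, 1 each of WT and rpt3-1 grown with and without thiamine. Per the labels' protocols, cells of a strain with GFP-cnp1 under the nmt1 promoter at lys1 were cultured for 18 h at 33 °C, shifted to 18 °C for 2 h and fixed with 3% formaldehyde for 35 min, and chromatin was sheared to a mean of 500 bp (300 to 1000 bp). Per the labels, the Cy5 channel held the DNA recovered with the GFP antibody and the Cy3 channel the input, on every array, so all ratios run the same way and there is no dye swap. The arrays lie on 1 slide, so slide and group are not confounded, and a fit with the slide as a block could not be run. Groups were taken from the sample labels.

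Spot intensity values were made by Agilent Feature Extraction 9.5.1.1, per the file headers: the processed signals had a fitted spatial background surface subtracted, were detrended multiplicatively and were dye-normalised with a linear factor, and mean and local background signals stand beside them. The deposited files also hold the log10 ratio of red over green that this software computed. The authors' deposited value table holds log2 values per probe; its scale and direction were worked out from its correlation with the log2 of the scanner ratio of the same array (0.72, 0.78, 0.85 and 0.97), whereas its normalisation and centring are not given in the sources used here. Its column medians were -0.05, -0.06, -0.09 and -0.14. It was closest to loess-normalised scanner ratios, with correlations of 0.95, 0.99, 0.99 and 1.00, and served as an alternative.

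The log2 of processed Cy5 over Cy3 signal was centred on each array's median probe, without loess or quantile normalisation, because a ChIP signal can shift many probes one way. Of 40579 probes, 39543 were well above background in both channels on all 4 arrays, and 37348 of these had no outlier mark on any array and were kept. The array design names a genome build from before the reference used here, so the 60 nt probe sequences were matched to that reference, which has chromosomes of 5579133, 4539804 and 2452883 bp, and all coordinates are those matches. Of the probes 39691 matched 1 place, 846 several and 42 none; 40455 were placed with a median spacing of 298 bp, and a probe with several matches was placed next to its neighbours in the array design where one match lay within 2000 bp of them.

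As the annotation used here gives no central core or repeat features, the Cnp1 domain was the longest run on each chromosome with a running median over 5 probes of at least 1 in WT with thiamine, by a rule fixed before the data were examined. Its edges are thus set on one of the arrays compared. The core is the part between the outermost tRNA genes within 15 kb of the midpoint, of which there are 6, 6 and 11. Flanks are the 0 to 10 kb and 10 to 50 kb outside the domain, and width is the same run measured on each array. Enrichment on the arms was counted over probes more than 50 kb from the domains, with Wilson intervals. Flank differences were set against 10000 random sets of 6 windows of 10 kb from the arms, and, after the data were seen, those of the first 5 kb against windows of 5 kb.

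A gene's value is the mean over probes in its body, for genes with at least 3 kept probes (4492 genes). The median difference of each of 13 gene lists was set against 10000 random lists of the same size matched on input signal in 10 bins, as a description of these arrays. The median difference over all genes between rpt3-1 and WT with thiamine was -0.14, against -0.018 after loess, 0.055 with quantiles, 0.069 with medians over probes and 0.022 in the deposited table, so list medians are read against random lists. The lists, fixed before the data were examined, hold histone, kinetochore and Cnp1 loading, proteasome, ribosomal protein, glycolysis, thiamine-regulated, chaperone, stress response, meiotic, flocculin and adhesin, phosphate and iron uptake and subtelomeric helicase genes, and Tf2 elements. Genes named in the text follow a rule fixed at the same time. It takes the 6 highest and 6 lowest differences of each of the 4 comparisons, among genes over 50 kb from the domains, the 2 members of each list with the largest difference between genotypes without thiamine, and cnp1, lys1, nmt1 and rpt3. Other members named as examples of a list, the genes next to the centromere domains and genes in the longest enriched regions were chosen after their values were seen.

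With 1 array per group no difference between 2 arrays has a test. The single test was limma's moderated test for an additive model of genotype and medium on gene values, with Benjamini-Hochberg adjustment. The script was tested on simulated data for the genotype effect with 200 of 4492 genes changed, in 20 simulations per size. It recovered 0.625%, 23.7% and 82.7% of genes changed by a log2 of 1, 2 and 3, and 75.2%, 16.6% and 10.3% of its calls were unchanged genes, more than the 5% aimed at; the prior degrees of freedom, estimated from 1 residual degree per gene, were infinite in 6, 3 and 3 of the 20 simulations. The share of recovered genes with the right direction was 100% at each size. Calls of this model in single settings therefore hold more false ones than their adjusted p states.

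Alternatives were normexp background correction with an offset of 50, loess within each array, centring on the chromosome arms, equal median absolute deviation, quantile normalisation between arrays, all probes, medians over probes, probes that match 1 place, the deposited value table, other region sizes, thresholds (1.5) and windows (9 probes or single probes), an intensity trend, bins of 1 kb and genes with 1 probe. Added after the data were seen were the ChIP channel alone, the core and the repeats in place of the whole domain and its 20 kb surroundings, flanks set from the edges on rpt3-1 without thiamine, and random lists matched also on the number of probes. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.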

Results

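The data describe where the centromere-specific histone Cnp1, the fission yeast form of CENP-A, sat along the chromosomes of wild-type cells and of the proteasome mutant rpt3-1. Rpt3 is an ATPase subunit of the regulatory particle of the proteasome. Cnp1 carried a GFP tag and was expressed from an added gene at lys1 under the nmt1 promoter, which thiamine represses and which is active in medium without it. Chromatin pulled down with an antibody against GFP was compared with input chromatin on tiling arrays, in both genotypes and in both media, which gives 4 groups with 1 array each. There are therefore no replicates, every difference below is a difference between 2 arrays, and a spread given beside a mean is the spread over probes or over centromeres and not between cultures. The added gene lies beside a region under study: lys1 (chromosome 1, 3739076 to 3743449) starts and ends to the left of centromere 1, with its nearer end 9.07 kb from the edge of the Cnp1 domain.

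The arrays differed in the brightness of the ChIP channel. The median background-subtracted ChIP brightness was 228 in WT with thiamine, 6354 in WT without thiamine, 2261 in rpt3-1 with thiamine and 8508 in rpt3-1 without thiamine, while the input brightness lay between 4623 and 6704. The WT array with thiamine stood apart from the other 3. On it 1128 of 34676 probes on the chromosome arms had a log2 ratio of at least 4, against 24, 12 and 24 on the others, and neighbouring arm probes were least alike, with a correlation of 0.11 against 0.39, 0.30 and 0.56. Its arm profile had a rank correlation of -0.12, -0.09 and 0.02 across probes with those of WT without thiamine, rpt3-1 with thiamine and rpt3-1 without thiamine (0.04, 0.12 and 0.02 after loess). Probes are not independent replicates, so these correlations describe the arrays only. The number of arrays limits the precision of all values.

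On all 4 arrays the mean over the centromere domains exceeded that of every class of region measured outside them. In WT without thiamine, where it was 2.55, some single arm genes were higher, such as SPBC337.11 at 2.97 and SPAC3A12.08 at 2.81. The core had 3.62 on that array. The Cnp1 domain, the longest run of enriched probes on each chromosome of WT with thiamine, covered 3752521 to 3790502 on chromosome 1, 1600267 to 1640830 on chromosome 2 and 1073437 to 1138193 on chromosome 3. These intervals hold the central core, which is bounded by tRNA genes, and the heterochromatic repeats on either side of it. Of the 239 probes in them, 200 match more than 1 place in the genome, so that signal from one repeat copy cannot be assigned to it. Gene values of the 4 genes of the experiment were below the domain mean on each array. They lay between -0.06 and 0.97 for cnp1, between 0.14 and 0.88 for lys1, between -0.05 and 0.20 for rpt3 and between -0.35 and 1.23 for nmt1, over 4, 11, 7 and 3 probes. Probes of cnp1 may also read the added GFP-cnp1 gene, so their signal cannot be assigned to either copy.

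**Figure D1:**
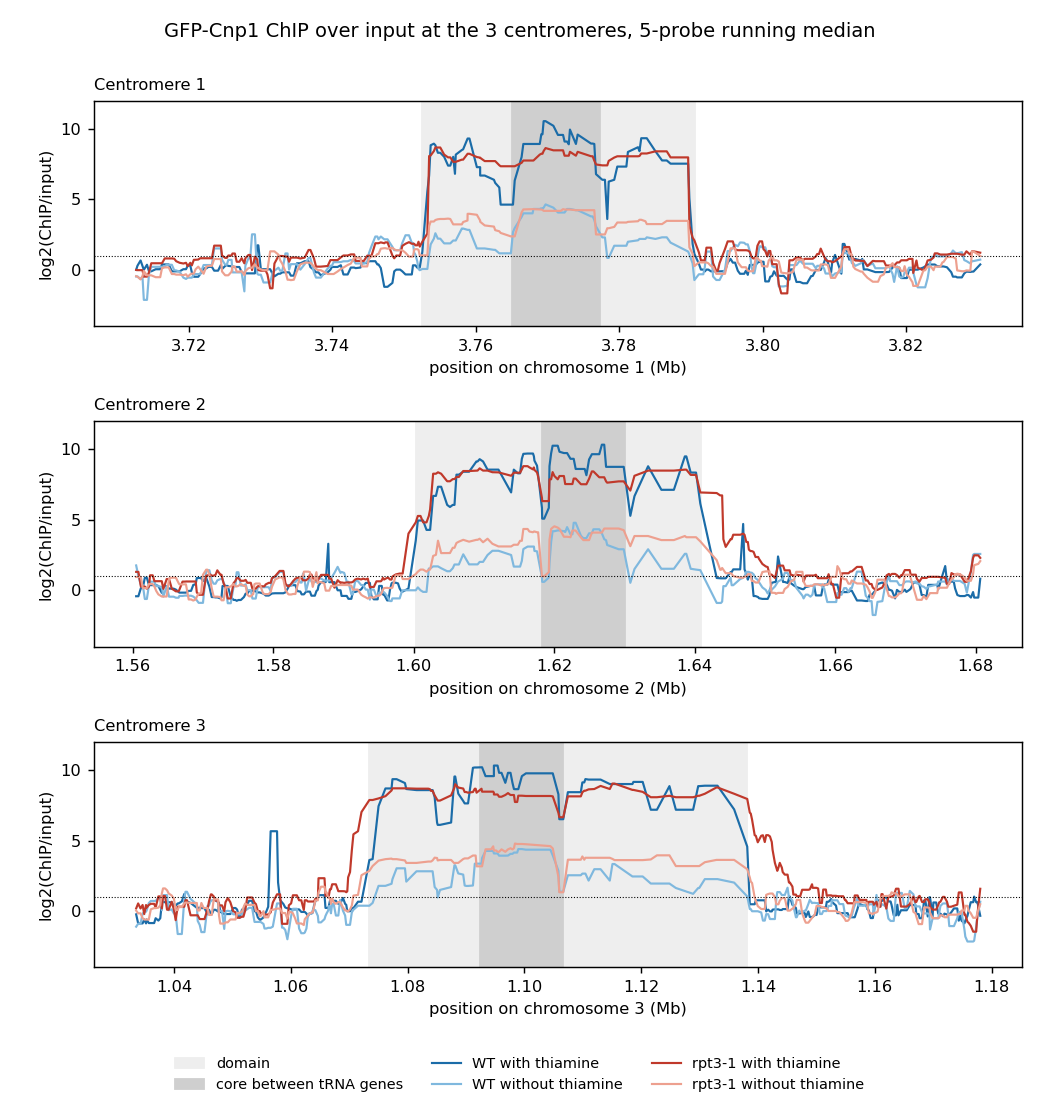
Running median over 5 probes of log2(ChIP/input), vertical axis, against the position in Mb, horizontal axis, at centromeres 1 to 3 and the 40 kb on either side, with 1 line per array. Pale grey marks the Cnp1 domain, dark grey the core between tRNA genes, and the dotted line a log2 ratio of 1. Both arrays with thiamine reach higher inside the domains than both arrays without, and the line of rpt3-1 with thiamine stays high past the right edges of centromeres 2 and 3.

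Did the distribution of Cnp1 differ between the genotypes with thiamine, which represses the promoter of its added gene? With thiamine, the mean log2 ratio over the 3 domains was nearly the same, 7.96 ± 2.35 in WT and 7.84 ± 1.30 in rpt3-1 (SD over 239 probes), a difference of -0.12. The clearest difference lay just outside. In the 10 kb on either side of the domains the mean was 0.55 ± 1.70 in WT and 1.98 ± 1.88 in rpt3-1 (SD over 181 probes). The difference of 1.44 was above 0 at 6 of 6 flanks and exceeded that of all 10000 random sets of 6 windows of the same length from the arms, of which the highest reached 0.25. None of 1150 single arm windows was as high. The domain edges were set on the WT array; with edges set on rpt3-1 without thiamine the difference was 1.05 ± 0.32 (SE over 6 flanks), again above 0 at 6 of 6 flanks.

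The difference beside the centromeres was uneven between flanks, and so was the number of probes that match several places. These were 5 of 33 to the right of centromere 3, 8 of 25 to the right of centromere 2 and 3 of 29 to the left of centromere 3. To the left of centromere 2 they were 1 of 31, and on both sides of centromere 1 they were 0. Signal on such probes cannot be assigned to the flank. Over all flanks together the difference of 1.44 stayed between 1.05 and 2.18 in 11 alternative settings, which include the use of only those probes that match 1 place. To the right of centromere 3 the mean was 0.45 in WT and 3.37 in rpt3-1, and ppc1, the nearest protein-coding gene on that side, had gene values of 0.54 and 2.91. To the right of centromere 2 the means were 1.29 and 3.45. The left flank of centromere 3 had 0.79 and 2.22, and the left flank of centromere 1 had -0.03 and 1.40, where the nearest gene per1 had gene values of 0.28 and 1.72. Differences were smaller to the right of centromere 1, with 0.52 and 1.00, and to the left of centromere 2, with 0.40 and 0.73, where the RNA polymerase gene rpb1 had gene values of 0.41 and 0.63. The signal in rpt3-1 was lower with distance, from 3.01 ± 0.47 (SE over 25 probes) in the first 2 kb to 2.30 ± 0.30 at 2 to 5 kb, 1.57 ± 0.14 at 5 to 10 kb and 0.65 ± 0.08 at 10 to 20 kb. In WT the same intervals gave 0.39 ± 0.28, 0.56 ± 0.22, 0.58 ± 0.18 and 0.51 ± 0.13. From 10 to 50 kb the means were 0.34 in WT and 0.56 in rpt3-1, and over the first 20 kb they were 0.53 and 1.32.

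**Figure D2:**
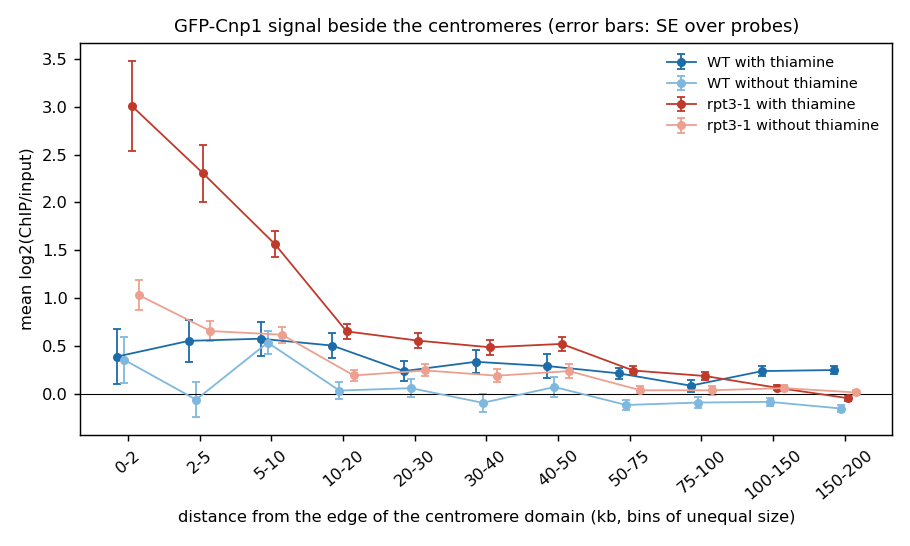
Mean log2(ChIP/input), vertical axis, in bins of distance from the edge of the nearest Cnp1 domain in kb, horizontal axis, with bins of unequal size; points are the 4 arrays and error bars the SE over probes. Only rpt3-1 with thiamine is above 1.5 between 0 and 10 kb, falling from 3.01 to 1.57.

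Inside the domains the core and the repeats differed in opposite directions with thiamine. Over the core the mean was 8.85 ± 2.04 in WT and 7.75 ± 1.06 in rpt3-1 (SD over 82 probes), and over the repeats 7.50 ± 2.37 and 7.89 ± 1.41 (SD over 157 probes). Domain width, measured on each array as the enriched stretch around the centromere, was larger in rpt3-1 at all 3 centromeres, with 42.2 kb against 38.0 kb at centromere 1, 53.5 kb against 40.6 kb at centromere 2 and 85.6 kb against 64.8 kb at centromere 3. The mean width was 60.5 ± 22.5 kb in rpt3-1 and 47.8 ± 14.8 kb in WT (SD over 3 centromeres); the domains used throughout were set on that WT array, whose mean width was 25.8 kb after loess. The stretch in rpt3-1 reached further by 10130 bp and 12137 bp to the right of centromeres 2 and 3, by 8709 bp, 3625 bp and 2851 bp to the left of centromeres 3, 1 and 2, and by 632 bp to the right of centromere 1. The near-equal level of the whole domain depended on the processing: its difference was 3.26 after loess and 3.35 in the authors' deposited value table. The core difference was 0.80 after loess, so the core was then higher in rpt3-1 and not lower. In the ChIP channel alone core and repeats were both lower in rpt3-1, by -1.68 and -1.71, while the input channel differed by -0.47 over the core and -1.99 over the repeats.

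**Figure D3:**
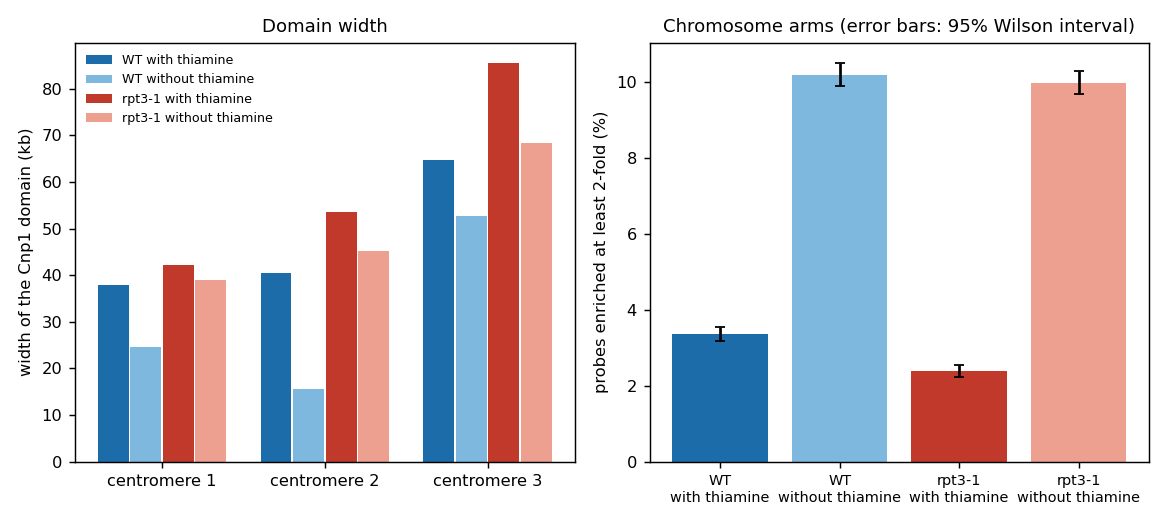
Left, width of the Cnp1 domain in kb (vertical axis) at each centromere (horizontal axis), with 1 bar per array. Right, percent of probes over 50 kb from the centromeres with a running median of at least 2-fold enrichment (vertical axis) on each array (horizontal axis), with 95% Wilson intervals; the arrays without thiamine stand at 10.2 and 9.98, those with thiamine at 3.35 and 2.38.

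Away from the centromeres, the 16 measured glycolysis genes had a median difference between rpt3-1 and WT with thiamine of 0.92 that exceeded 99.99% of random lists of similar input signal. The aldolase gene fba1 had -0.55 in WT and 1.64 in rpt3-1, the enolase gene eno101 -0.37 and 1.63, and the pyruvate kinase gene pyk1 -0.45 and 1.29; 12 of the 16 were above 0. Kinetochore and Cnp1 loading genes differed the other way, with a median of -0.69 over 25 genes, lower than 99% of random lists (percentile 1); examples are sim3 at 1.69 and 0.35 and ndc80 at 0.96 and -0.24. Tf2 elements had a median of -2.40 (percentile 0.03) over 3 of 13 members. All 6 probes of Tf2-4 and all 6 of Tf2-6 match several places, so these members may share signal. Percentiles of this list, here and below, can thus overstate how far it lies from lists of separate genes. The medians of these lists depended on the processing: kinetochore and Cnp1 loading genes had -0.20 after loess and -0.13 in the deposited table, and Tf2 elements -0.97 and -0.11, while glycolysis genes had 0.62 and 0.75. The other lists lay nearer to random ones. Median differences and percentiles were -0.06 (67.7) for 8 histone genes, 0.06 (83.8) for 28 proteasome genes, 0.04 (10.0) for 33 of 131 ribosomal protein genes, 0.06 (47.1) for 9 thiamine-regulated genes, 0.24 (71.2) for 13 chaperone genes, -0.08 (43.9) for 11 stress response genes, -0.35 (31.7) for 14 meiotic genes, -0.30 (9.72) for 8 flocculin and adhesin genes and 0.03 (47.0) for 9 phosphate and iron uptake genes. Of the subtelomeric helicase genes 1 was measured, tlh1, with 0.97 and 1.02. The medians of histone, of meiotic and of flocculin and adhesin genes turned positive after loess (0.07 for meiotic and 0.60 for flocculin and adhesin genes) and in the deposited table.

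Among single genes the lowest differences between rpt3-1 and WT with thiamine all came from high values in WT. They were -6.79 for laf2 (chromosome 3, 399004 to 400502), -5.02 for arp10, -4.92 for ost3, which encodes an oligosaccharyltransferase subunit, -4.34 for SPAC823.09C, -3.95 for SPAC1142.09 and -3.89 for erf1. In WT the 5 probes of laf2 had a median of 7.32, close to the level of the centromere domains, and on the other 3 arrays laf2 had 1.27, 0.21 and 0.24. For erf1 the WT mean of 3.24 rested on a few of 7 probes, whose median was 1.04. The highest differences were 2.19 for rlc1, a myosin light chain gene, 2.16 for SPAC56F8.12, 2.12 for the transcription factor gene rsv1, 2.06 for SPAC26F1.11, 2.05 for SPAC57A7.07C and 2.04 for SPBC337.11. After loess the 6 lowest lay between -3.60 and -2.03 and the 6 highest between 1.39 and 2.40. Of 4492 genes, 188 differed by more than 1 and 632 by less than -1.

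Most other regions were lower in rpt3-1 than in WT with thiamine. The outer 50 kb of the chromosomes had 0.66 in WT and 0.12 in rpt3-1, the outer 100 kb of chromosomes 1 and 2 had 0.47 and 0.0021, and the rDNA had 1.92 and 1.13. Tf2 retrotransposons differed most, with 1.23 in WT and -0.92 in rpt3-1 over 26 probes, of which 24 match several places. Intergenic regions upstream of genes had 0.34 and -0.33, gaps between convergent genes 0.50 and -0.37, and coding gene bodies 0.18 and -0.06. The mating-type region had 0.24 and 0.12, an order that turned after loess and in the deposited table, and 11 probes in tRNA genes outside the centromeres 1.33 and 1.40. The subtelomere difference of -0.54 turned to 0.53 after loess, the upstream intergenic difference was 0.0068 and the rDNA difference 5.05, and the Tf2 difference was -0.06 after loess and 0.39 in the deposited table.

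Was the pattern the same in the other medium? Without thiamine, the domain mean was higher in rpt3-1, 3.48 ± 1.09 against 2.55 ± 1.47 in WT (SD over 239 probes), by 0.88, 0.95 and 0.93 at centromeres 1, 2 and 3. The repeats held nearly all of this difference, with 2.00 in WT and 3.30 in rpt3-1, while the core had 3.62 and 3.82. On the repeats the ChIP channel alone differed by 0.20 and the input channel by -1.09. Domains were wider in rpt3-1 at each centromere, with 38.9 kb against 24.6 kb, 45.3 kb against 15.6 kb and 68.3 kb against 52.7 kb, for means of 50.8 ± 15.5 kb and 30.9 ± 19.3 kb (SD over 3 centromeres). Over 9 alternative settings these means ranged from 28.8 to 53.7 kb in rpt3-1 and from 13.2 to 47.0 kb in WT. At centromere 2 of WT the enriched stretch ended at 1617744, beside the tRNA genes at the left of the core, so its width there leaves out the core.

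Beside the centromeres the difference without thiamine depended on the distance. The 10 kb flanks had 0.33 in WT and 0.69 in rpt3-1, a difference of 0.35 that was above 0 at 4 of 6 flanks and exceeded 88.3% of the random sets of arm windows. In the first 5 kb, an interval set against random sets after its values were seen, the difference was 0.70, above 0 at 5 of 6 flanks. It was above 99.7% of the random sets of 5 kb windows, which were not matched on input signal. With thiamine the difference in the first 5 kb was 2.02. Without thiamine it was 1.38 and 1.22 to the right of centromeres 3 and 2, but -0.04 and 0.18 to the left and right of centromere 1. To the right of centromeres 3 and 2, 5 of 16 and 6 of 9 probes match several places, against 0 of 15 and 0 of 13 beside centromere 1. By distance, WT had 0.36 ± 0.24, -0.06 ± 0.18 and 0.54 ± 0.12 and rpt3-1 1.03 ± 0.16, 0.66 ± 0.11 and 0.62 ± 0.08 (SE over probes) at 0 to 2, 2 to 5 and 5 to 10 kb. Over the first 20 kb the means were 0.19 and 0.44, and from 10 to 50 kb 0.02 and 0.22. The gene per1 had 1.77 in WT and 1.17 in rpt3-1, and ppc1 had 1.01 and 0.73. With probes that match 1 place the difference of 0.92 over the domains became 0.17, and in the ChIP channel alone it was 0.093. Probes that match 1 place were 31 of 82 in the core and 8 of 157 in the repeats. The value of 0.17 thus describes mostly the core, which differed by 0.20 over all its probes.

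In the absence of thiamine intergenic regions differed between the genotypes. Upstream intergenic regions had -0.31 in WT and 0.76 in rpt3-1 over 6795 probes, and gaps between convergent genes -0.37 and 0.61 over 489 probes, while coding gene bodies had -0.04 in both. The share of upstream intergenic probes enriched at least 2-fold was 13.1% in WT and 28.4% in rpt3-1, and that of coding probes 9.41% and 5.31%. Tf2 elements had -1.60 and -0.16, the outer 50 kb of the chromosomes 0.15 and 0.58, the outer 100 kb 0.03 and 0.40, the mating-type region 0.15 and 0.56, and tRNA genes 0.52 and 0.65. The rDNA was lower in rpt3-1 by -0.60, a difference that was 0.14 after loess, where the upstream intergenic difference of 1.08 was 0.50.

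Chaperone genes stood out among the lists without thiamine. Their median difference was -1.16, below all 10000 random lists, and 12 of 13 were lower in rpt3-1: hsp78 had 0.72 in WT and -1.11 in rpt3-1, ssa1 differed by -1.63, and hsp104 had 1.01 and -0.55. Stress response genes had a median of -0.68 (percentile 0.33), with 10 of 11 lower, among them the catalase gene ctt1 at 1.36 and 0.10 and the trehalase gene ntp1 at 0.07 and -1.12. All 8 histone genes were lower, with a median of -0.57 (percentile 0.57); htb1 had -1.26 and -2.15 and hta1 -1.04 and -1.94. Proteasome genes had a median of 0.19 (percentile 99.1), with rpn8 at -0.68 and 0.31 and rpn9 at -0.97 and -0.04. Tf2 elements had a median of 1.42 over 3 members, whose probes mostly match several places, above all random lists. Kinetochore and Cnp1 loading genes had 0.35 (89.3), with mis6 at -2.17 and -0.23 but mis16 lower in rpt3-1 by -1.17. Ribosomal protein genes had -0.46 (51.9), glycolysis genes -0.48 (45.2), thiamine-regulated genes -0.56 (9.91), meiotic genes -0.01 (19.9), flocculin and adhesin genes -0.26 (77.7) and phosphate and iron uptake genes -0.04 (89.8). The medians of glycolysis (0.083) and of flocculin and adhesin genes (0.23) turned positive after loess, that of proteasome genes was -0.055 with quantiles, and that of kinetochore and Cnp1 loading genes -0.0015 in the deposited table.

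Single genes with the highest differences between rpt3-1 and WT without thiamine were the decapping gene dcp1 at 3.30, with -2.44 in WT and 0.86 in rpt3-1, dpb3, a DNA polymerase subunit gene, at 2.60, the RNA polymerase subunit gene rpb8 at 2.47, SPBC336.16 at 2.46, SPBC1271.08C at 2.44 and SPBC15D4.11C at 2.33. The lowest were SPAC3A12.08 at -2.23, the pyruvate decarboxylase gene pdc102 at -2.13, with 2.76 in WT and 0.63 in rpt3-1, SPAC186.07C at -2.10, SPBC23G7.10C at -2.08, SPAC750.08C at -2.05 and SPBC530.07C at -1.92. All 3 probes of SPAC750.08C match several places. After loess the 6 highest lay between 1.35 and 2.40 and the 6 lowest between -2.05 and -1.27. The thiamine-repressed gene nmt1 had 1.23 in WT and 0.13 in rpt3-1, and cnp1 0.02 and 0.97. Probes of cnp1 may also read the added GFP-cnp1 gene at lys1.

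How did the profile in WT differ between the media? Expression of the added gene was not measured, and the ChIP brightness of these arrays differed, at 228 with and 6354 without thiamine. The domain mean was 7.96 with and 2.55 without thiamine, a difference of -5.40, with similar values over the core, -5.23, and the repeats, -5.50. The log2 ratio is centred on each array's median probe, so it gives enrichment over the chromosome arms and not the amount of bound Cnp1. Near flanks had 0.55 and 0.33, and the mean domain width was 47.8 kb with and 30.9 kb without thiamine, the latter from 13.2 to 47.0 kb over 9 alternative settings. Of the probes over 50 kb from the centromeres, 3.35% (95% Wilson interval 3.17 to 3.54, counting error only) were enriched at least 2-fold with thiamine and 10.2% (9.89 to 10.5) without, in 475 and 902 regions, of which 4 and 46 held at least 10 probes. The contrast in these shares was nearly lost with normexp, with 8.75% with and 9.71% without thiamine, and with equal scale, with 4.55% and 4.78%. The size of the domain difference depended on the processing, with -1.65 after quantile normalisation and -2.05 after loess.

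The longest enriched regions on the arms of WT without thiamine included the left end of chromosome 1 with tlh1 (112 to 10249), a stretch of chromosome 3 with agp3 and dpe2 (2304657 to 2311063), a stretch of chromosome 2 with cup1 (2195336 to 2200715), and the git3 and rec7 region of chromosome 3 (1545156 to 1548863). Over these the mean was 1.58, 1.18, 1.69 and 1.77 without thiamine, against 0.73, -0.19, -0.10 and -0.17 with it, as regions chosen on the array without thiamine. Among the gene lists, Tf2 elements had a median of -3.19 (percentile 0.01), which was -1.70 after loess and -0.62 in the deposited table. Histone genes had a median of -0.80 (4.09), phosphate and iron uptake genes -0.50 (2.73), ribosomal protein genes -0.10 (2.13), proteasome genes -0.42 (4.97) and kinetochore and Cnp1 loading genes -0.64 (6.50), the last of which was -0.21 after loess. Glycolysis genes had -0.01 (12.2), thiamine-regulated genes -0.03 (32.0), chaperone genes 0.38 (75.9), stress response genes -0.24 (23.9), meiotic genes -0.46 (23.6) and flocculin and adhesin genes -0.39 (7.59), the last of which was 0.015 after loess and 0.47 with medians over probes.

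Single genes with the highest difference between media in WT were SPBC337.11 at 3.31, rlc1 at 3.30, SPAC3A12.08 at 3.27, the dUTPase gene dut1 at 3.22, SPAC56F8.12 at 3.22 and SPAC26F1.11 at 2.93. The lowest were laf2 at -5.73, ost3 at -5.13, SPAC1142.09 at -4.86, trs23 at -4.71, arp10 at -4.64 and SPAC823.09C at -4.27, all with high values in WT with thiamine. After loess these lay between -3.36 and -2.61 and the 6 highest between 2.33 and 3.58. Both comparisons against WT with thiamine share the noise of that array, so genes that stand out in both are not independent evidence.

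Was the effect of the medium the same in rpt3-1? There the domain mean was 7.84 with and 3.48 without thiamine, a difference of -4.37, which was -1.18 with quantiles. Near flanks had 1.98 and 0.69, lower without thiamine at 6 of 6 flanks, and the difference of -1.30 lay below all 10000 random sets of arm windows. The mean domain width was 60.5 kb with and 50.8 kb without thiamine. On the arms 2.38% (2.23 to 2.55) of probes were enriched at least 2-fold with and 9.98% (9.68 to 10.3) without thiamine, in 247 and 789 regions, of which 6 and 61 held at least 10 probes. With quantiles the shares were 5.67% and 8.60%. With thiamine these regions included those at eno101 (chromosome 2, 2198444 to 2202103), adh1 (chromosome 3, 1589112 to 1592568) and pyk1 with ppc89 (chromosome 1, 3845754 to 3848746), with region means of 1.65, 1.71 and 1.28, against 1.74, 1.11 and 0.32 without thiamine. The gene values themselves were 1.63 with and -0.18 without thiamine for eno101, 0.85 and -0.25 for adh1, and 1.29 and -0.96 for pyk1. Without thiamine the enriched regions included a stretch of chromosome 3 with new22 (30539 to 41460), the left and right ends of that chromosome and the txc1 and sgo1 region of chromosome 2 (963423 to 967923), at 1.59, 1.85, 1.88 and 1.59, against 0.58, 0.85, 0.56 and 0.37 with thiamine. Each region was chosen on the array it is listed for.

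Several lists were lower without than with thiamine in rpt3-1. Medians lay below all 10000 random lists for chaperone genes at -1.13, glycolysis genes at -1.04, histone genes at -1.01, stress response genes at -0.85 and ribosomal protein genes at -0.73, and 0 of 8 histone, 2 of 16 glycolysis, 2 of 13 chaperone, 1 of 11 stress response and 4 of 33 ribosomal protein genes had a difference above 0. Tf2 elements had 0.72 (percentile 99.95), kinetochore and Cnp1 loading genes 0.32 (82.8), phosphate and iron uptake genes -0.45 (3.43), proteasome genes -0.19 (7.03), thiamine-regulated genes -0.17 (52.4), meiotic genes 0.05 (22.1) and flocculin and adhesin genes -0.23 (47.5). These differences share arrays with those between genotypes. On rpt3-1 without thiamine the levels of chaperone, stress response and histone genes were at percentiles 0.1, 0.01 and 0 of random lists. On rpt3-1 with thiamine that of glycolysis genes was at percentile 100. Lists that stand out in both comparisons are thus not independent evidence. Single genes with the lowest difference were knh2 at -2.62, the histone gene htb1 at -2.35, pyk1 at -2.25, the histone gene hht2 at -2.19, gas2 at -2.13 and the helicase gene sum3 at -2.10. The highest were mug16 at 2.94, SPBP8B7.31 at 2.92, dpb3 at 2.81, smf1 at 2.40, SPBC15D4.11C at 2.34 and mim1 at 2.23. After loess the 6 lowest lay between -2.47 and -1.60 and the 6 highest between 1.30 and 2.60. Upstream intergenic regions had -0.33 with and 0.76 without thiamine, convergent gaps -0.37 and 0.61, the outer 50 kb of the chromosomes 0.12 and 0.58, and Tf2 elements -0.92 and -0.16.

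**Figure D4:**
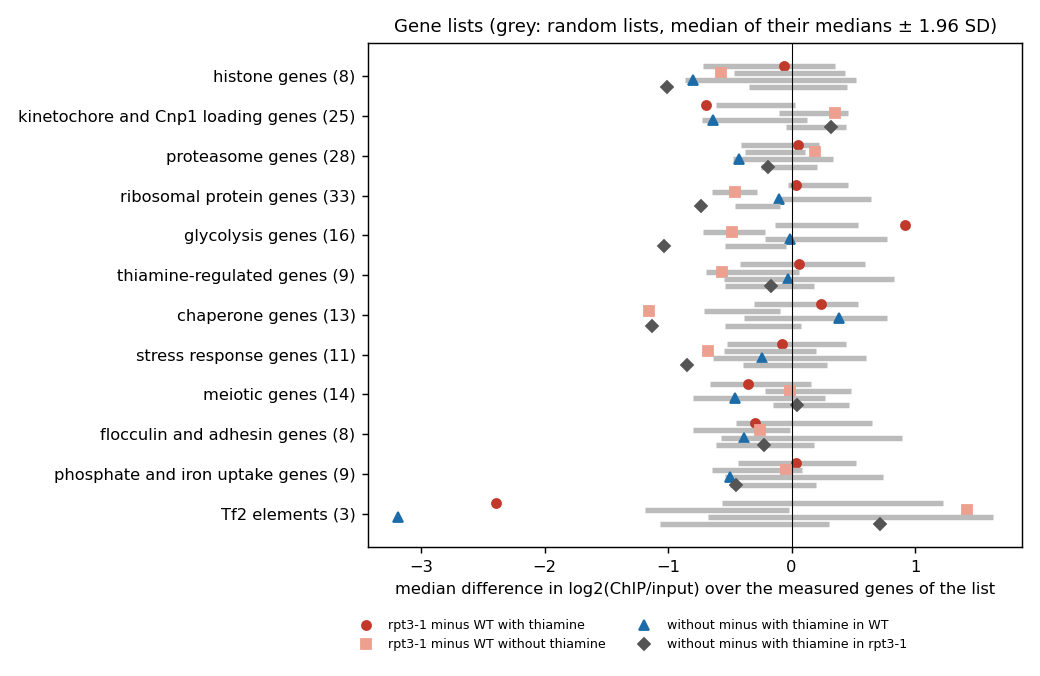
Median difference in log2(ChIP/input) over the measured genes of each list, horizontal axis, for the 4 comparisons between arrays, with the number of genes beside each list name on the vertical axis. Symbols are the comparisons and grey bars the medians of random lists matched on input signal, as the central 95% of a normal curve with their SD. Chaperone genes lie at -1.16 and -1.13 in the comparisons that involve rpt3-1 without thiamine, and glycolysis genes at 0.92 in rpt3-1 against WT with thiamine.

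Did any gene differ between genotypes in both media? An additive model over the 4 arrays, with genotype and medium as terms and 1 residual degree of freedom, called 0 of 4492 genes for genotype and 0 for medium with limma at an adjusted p of 0.05. At an unadjusted p of 0.05, limma called 60 genes for genotype and 133 for medium. In other settings limma called at most 4 genes for genotype, with an intensity trend, and 0 to 48 for medium, with 48 in the deposited table, 33 of the 1 kb bins and 12 genes with an intensity trend. Lowest p-values in limma were those of SPAP11E10.01 at -2.19 and laf2 at -3.91 for genotype, and of rlc1 at 2.41 and mei3 at 2.11 for medium, none past adjustment (adjusted p = 1.00 and 0.998). In this model an effect of genotype that differs between media counts as error.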

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

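Tests on loess values, on the medium without thiamine and on the ChIP channel and unique probes were chosen after the patterns they bear on were seen; tests with other domain edges, GC content and input signal were set out before their results, but their SEs, and the margin of 1 SE beyond the bound by which they are read, were chosen after the values were seen. No difference between differences below was tested, because each group has 1 array.

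Beside the centromeres, the 10 kb flanks were higher in rpt3-1 than in WT with thiamine by 1.44. A signal-dependent bias between channels is argued against by a difference of 1.79 after loess, above the highest random set at 0.50. In the input channel the flanks differed by -0.04. Edges set on the WT array could lower WT values just outside them. With edges from rpt3-1 without thiamine the difference was 1.05 ± 0.32 (SE over 6 flanks), above the highest random set at 0.25. It was also, by just over 1 SE but under 2, above the 0.72 below which edges would account for most of it. Those edges reached beyond the WT ones by only 1137, 0 and 2732 bp to the left of centromeres 1, 2 and 3. To the right they did so by -244, 4687 and 829 bp. Both sets of flanks thus share most of their sequence, so this test cannot decide on edges as a cause. Variation between single cultures or arrays stays open. Without thiamine the difference of 0.35 lay at percentile 88.3 of random arm windows, and that of 0.70 in the first 5 kb at percentile 99.7. The random windows were not matched on input signal. In the first 5 kb this signal was -0.86 in WT and -0.75 in rpt3-1 without thiamine, against -0.14 and -0.03 over coding gene bodies. Upstream intergenic regions, also low in input, differed by 1.08 between these arrays, so the percentile of 99.7 cannot decide. A spread of Cnp1 that depends on Rpt3 cannot be told apart from such variation with 1 array per group.

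Inside the domains, the repeats were higher and the core lower in rpt3-1 with thiamine, with differences of 0.40 and -1.10 (0.80 for the core after loess). In the ChIP channel alone the gap between these differences was -0.023, so a lower input signal on the repeats of the rpt3-1 array may account for it. With probes that match 1 place the gap was 2.49, but only 8 of 157 repeat probes do so, none of them at centromere 3, so shared probe sequences stay open as a cause. An effect of genotype on the repeats was not tested apart from this. The input channel, which the comparisons use only as a denominator, held a signal of its own there, with repeats at -0.85 in WT and -2.84 in rpt3-1, a difference of -1.99.

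Intergenic regions were higher than coding ones in rpt3-1 against WT without thiamine, a gap of 1.08. With GC content matched the gap was 0.93 ± 0.02 (SE from resampled blocks of 50 kb), and with input signal matched 0.58 ± 0.02. The bound was 0.54, below which a factor would account for most of the gap. With each matched alone a gap remained, which argues against either as the whole cause. Input signal removed much of the gap, and its value of 0.58 exceeded the bound only narrowly, by over 1 SE but under 2. After loess the upstream intergenic difference was 0.50. The ratio's rank correlation with own input on the arms was -0.32 in WT with, 0.27 in WT without, 0.37 in rpt3-1 with and -0.34 in rpt3-1 without thiamine. Upstream intergenic means were 0.34, -0.31, -0.33 and 0.76, so a dependence on signal that differs between arrays stays open. An effect of genotype was not tested apart from variation between arrays.

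Many results had opposite signs in the 2 media or in the 2 genotypes. The difference without thiamine exceeded that with thiamine, in rpt3-1 against WT, by 1.04 over the central domain and 1.30 over the core. In the comparison of genotypes and in that of media between genotypes, where the gap is the same by arithmetic, it was 0.97 in the outer 50 kb of the chromosomes, 0.84 in the outer 100 kb, 1.74 in upstream and 1.86 in convergent intergenic regions, 3.61 in Tf2 elements and 0.53 in the mating-type region. Between media it was 0.24 in coding gene bodies and 0.19 in the rDNA. Most of these opposite signs depended on the processing: of the 16 pairs of differences over regions, 2 stayed opposite after loess, both of Tf2 elements, and 2 in the deposited table, those of convergent regions between genotypes and of Tf2 elements between media. Over the domain the genotypes then differed by 3.26 with and 1.29 without thiamine after loess, and by 3.35 and 1.21 in the deposited table.

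Gene list medians were opposite in the same way. Between genotypes the gap was 3.81 for Tf2 elements, -1.40 for chaperone genes, -1.40 for glycolysis genes, 1.04 for kinetochore and Cnp1 loading genes, -0.075 for phosphate and iron uptake genes, -0.50 for ribosomal protein genes and -0.62 for thiamine-regulated genes. Between media it was 3.91 for Tf2 elements, -1.51 for chaperone genes, 0.95 for kinetochore and Cnp1 loading genes and 0.51 for meiotic genes. Of these 11 pairs of list medians, 8 stayed opposite after loess and 7 in the deposited table. Glycolysis, meiotic and phosphate and iron uptake genes did not in either, nor kinetochore and Cnp1 loading genes between genotypes in the deposited table. The medians of phosphate and iron uptake genes, 0.03 and -0.04, were smaller than the SD of random lists, 0.24 and 0.19. The gap was -0.55 for lys1, -2.09 for nmt1 and -0.42 for rpt3, where 3 of 5 pairs stayed opposite after loess and 1 in the deposited table.

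Of 58 other named genes, 42 had opposite signs in the pair of comparisons they were chosen for; signs in the other pair were not counted. Most were chosen for an extreme difference, which favours such a gap. Of the 42 genes, 32 had opposite signs after loess and 34 in the deposited table, in at least 1 of the pairs counted. Some signs rested on few probes. In WT with thiamine rpn8 and gsf2 had highest probes of 5.66 and 5.55 but medians over probes of -0.51 and 0.24, against -0.34 and 0.39 in rpt3-1. For mcp7 these medians were -0.61 and -0.29. By medians these genes were thus higher in rpt3-1 in both media. The gap was positive for dcp1 at 4.05, mug16 at 3.64, dpb3 at 4.10, rpb8 at 3.77, SPBC336.16 at 3.82, smf1 at 3.62, SPBC1271.08C at 3.59, SPBC15D4.11C at 3.00, mim1 at 4.13, mis6 at 3.23, mcp7 at 1.57, rec11 at 1.84, rpn8 at 1.69, thi5 at 1.95, gsf2 at 1.45, Tf2-4 at 4.55 and Tf2-6 at 4.18. It was also positive for the genes with high values in WT with thiamine, laf2 at 5.76, arp10 at 5.12, ost3 at 6.06, SPAC823.09C at 4.59, trs23 at 5.25, SPAC1142.09 at 5.55 and erf1 at 4.31. It was negative for SPAC56F8.12 at -3.91, rsv1 at -3.56, SPAC26F1.11 at -2.63, SPAC57A7.07C at -2.07, SPBC337.11 at -3.45, hsp78 at -2.15, pgi1 at -1.67, mis16 at -1.96, fio1 at -0.97, rpl101 at -1.50, ctt1 at -2.65, tlh1 at -1.17, SPAC3A12.08 at -2.61, htb1 at -1.71, SPAC186.07C at -3.18, pyk1 at -2.73, SPAC750.08C at -2.16 and SPBC530.07C at -2.27.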

How the results depend on the processing

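Chosen after the data were seen were the ChIP channel alone, the core or repeats in place of whole regions, domain edges from rpt3-1 without thiamine and random lists matched also on probe number; the other alternatives were planned. A block for the slide was not run, because all arrays lie on 1 slide. Beyond the additive model of genotype and medium, no analysis of paired replicates was possible, because each group has 1 array. Of 1866 alternative values of 210 results, 1432 were counted as within the spread (over flanks or centromeres, probes, random lists, or the Wilson interval), 381 moved beyond it and 53 turned the direction of a value larger than its spread. Smaller values that changed sign are counted by how far they moved. Counts of genes called by limma were judged by their ratio instead. Domain values of single centromeres relative to the array mean are on another scale and count among the 1432 by rule, so they say nothing about stability. The near-flank difference between rpt3-1 and WT with thiamine stayed between 1.05 and 2.18 in its 11 alternatives, and that between media in rpt3-1 between -1.81 and -0.93. ChIP signal limits precision most in WT with thiamine, where 97.95% of probes were well above background at a median of 228. Unless stated, the cause of a change was not tested.

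For rpt3-1 against WT with thiamine, the domain difference of -0.12 was 0.039 with normexp, 3.26 after loess, 0.013 with equal scale, 0.88 with quantiles, -0.51 with medians, -1.07 with probes of 1 place, 3.35 in the deposited table, -1.70 in the ChIP channel alone and -1.10 over the core. Without thiamine the difference of 0.92 was 1.29 after loess, 1.90 with equal scale, 1.34 with quantiles, 1.00 with medians, 0.17 with probes of 1 place, 1.21 in the deposited table, 0.093 in the ChIP channel alone and 0.20 over the core. Between media in WT, -5.40 was -5.01 with normexp, -2.05 after loess, -7.17 with equal scale, -1.65 with quantiles, -6.02 with medians, -1.83 in the deposited table and -4.73 in the ChIP channel alone. Between media in rpt3-1, -4.37 was -4.03 after loess, -5.28 with equal scale, -1.18 with quantiles, -3.88 with probes of 1 place, -3.97 in the deposited table, -2.94 in the ChIP channel alone and -3.93 over the core. Probes of 1 place were 31 of 82 in the core and 8 of 157 in the repeats, so their values describe mostly the core.

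Over the outer 20 kb, the difference of 0.80 with thiamine was 1.54 with quantiles, and the repeats in its place gave 1.30 (for 0.26) without thiamine, -5.50 (for -0.34) between media in WT and -4.60 (for -0.88) in rpt3-1. From 10 to 50 kb, quantiles and medians gave 0.85 and 0.68 (for 0.21) with thiamine, -0.018 and -0.012 (for 0.20) without, 0.064 and 0.10 (for -0.32) between media in WT and -0.80 and -0.59 (for -0.34) in rpt3-1.

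In the outer 50 kb of the chromosomes, rpt3-1 against WT with thiamine gave 0.53 after loess, -0.0070 with quantiles and 0.56 in the deposited table (for -0.54), and the media in WT 0.58 after loess and 0.64 in the deposited table (for -0.51). In the outer 100 kb the values were 0.12, 0.013 and 0.14 (for -0.46), and 0.19 and 0.20 (for -0.44).

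Between genotypes with thiamine, coding gene bodies gave 0.048 with quantiles and 0.071 with medians (for -0.24), upstream intergenic regions 0.0068 after loess and 0.017 in the deposited table (for -0.67), convergent regions 0.013 after loess (for -0.88), Tf2 elements 0.39 in the deposited table (for -2.16), and the rDNA 5.05 after loess, 0.28 with quantiles and 4.77 in the deposited table (for -0.79). Without thiamine the rDNA gave 0.14 after loess (for -0.60). Between media in WT, coding bodies gave 0.075 with quantiles and 0.10 with medians (for -0.22), upstream regions 0.15 after loess and 0.13 in the deposited table (for -0.65), and convergent regions 0.16 and 0.074 (for -0.87). In rpt3-1 coding bodies gave -0.0069 with normexp, -0.029 after loess, -0.20 with quantiles, -0.16 with medians and -0.032 in the deposited table (for 0.02).

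Mean domain width was 25.8 kb after loess (for 47.8) in WT with thiamine, 13.2 to 47.0 kb over 9 alternatives (for 30.9) in WT without, and in rpt3-1 without 31.3 kb at a threshold of 1.5 and 28.8 kb with single probes (for 50.8). The percent of arm probes enriched was, in WT with thiamine (3.35), 8.75 with normexp, 1.55 after loess, 4.55 with equal scale, 4.14 with all probes, 1.14 at a threshold of 1.5, 1.02 with 9-probe windows and 13.5 with single probes. In WT without (10.2) it was 9.71, 6.31, 10.6 centred on the arms, 4.78 with equal scale, 7.24 with quantiles, 3.30, 6.35 and 17.8, so that the contrast between media in WT was nearly lost with normexp and with equal scale. In rpt3-1 with thiamine (2.38) it was 1.86, 1.48, 3.77 with equal scale, 5.67 with quantiles, 0.366, 1.27 and 7.26. In rpt3-1 without (9.98) it was 9.54, 9.57, 10.5 centred on the arms, 11.7 with equal scale, 8.60 with quantiles, 10.6 with all probes, 3.89, 6.42 and 15.6.

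Among genes and lists, nmt1 gave 0.027 in the deposited table (for -0.51) between media in rpt3-1. Between genotypes without thiamine, kinetochore and Cnp1 loading genes gave -0.0015 in the deposited table (for 0.35), proteasome genes -0.055 with quantiles (for 0.19), glycolysis genes 0.083 after loess and 0.027 in the deposited table (for -0.48), and flocculin and adhesin genes 0.23 and 0.20 (for -0.26). With thiamine, meiotic genes gave 0.070 after loess, 0.015 with medians and 0.027 in the deposited table (for -0.35), and flocculin and adhesin genes 0.60, 0.45 with quantiles, 0.44 with medians and 0.73 (for -0.30). Between media in WT the latter gave 0.015, 0.095 with quantiles, 0.47 with medians and 0.12 (for -0.39). With limma at an adjusted p of 0.05, genotype called 1 gene with normexp, 1 with medians, 1 in the deposited table and 4 with an intensity trend (for 0), and medium 1 with quantiles, 48 in the deposited table, 12 with an intensity trend and 33 of the 1 kb bins (for 0).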

Other observations

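The values in this part were chosen after the data were seen, and no test was run on them.

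The tRNA genes that bound the centromere cores carried less Cnp1 signal than the cores. Over 23 probes within 500 bp of the tRNA genes at 6 boundaries, the mean was 6.005 against 8.85 over the core in WT with thiamine, 1.83 against 3.62 in WT without, 6.81 against 7.75 in rpt3-1 with and 2.28 against 3.82 in rpt3-1 without thiamine. The left boundary of centromere 1 had 2.69 in WT and 6.65 in rpt3-1 with thiamine, over 3 probes, with lowest probes at 0.43 and 5.86. The right boundary of centromere 2 had 4.43 and 5.41 over 2 probes, and that of centromere 3 had 6.15 and 5.95 over 4.

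Along the arms, the profiles of WT without thiamine and rpt3-1 with thiamine were the most alike, with a rank correlation across probes of 0.69 (0.50 after loess), against 0.35 (0.48) between both arrays without thiamine and 0.23 (0.30) between both rpt3-1 arrays. On WT without and rpt3-1 with thiamine the arm ratios also rose with their own input signal, with rank correlations of 0.27 and 0.37, and with GC content, with 0.17 and 0.21. On WT with and rpt3-1 without thiamine these were -0.32 and -0.34 for input and -0.16 and -0.07 for GC content. The likeness was not tested apart from this shared dependence. Probes are not independent replicates. Of the arm probes enriched at least 2-fold, 617 were shared by WT without and rpt3-1 with thiamine, where 87.8 would be shared by independent sets, and 1277 by both arrays without thiamine, where 367 would be. Both rpt3-1 arrays shared 502, where 85.9 would be. The ratios of shared to independent counts were 7.03, 3.48 and 5.84 in this order. In rpt3-1 without thiamine 28.4% of upstream intergenic probes and 5.31% of coding probes were enriched, and in WT without thiamine 13.1% and 9.41%. Of the 38 rDNA probes, 100% were enriched in WT with thiamine and 65.8% in rpt3-1 without, and all of them match several places.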
